A study of Homo sapiens with 6 samples.

How the data were processed

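RNA was measured on human gene expression microarrays in 6 subcutaneous tumours grown in nude mice from DLD1 cells, a human colorectal adenocarcinoma line. Per the labels, 3 tumours came from mice given Dox (doxycycline) in the drinking water for 21 days and 3 from mice given none. The series title names a YAP-S127D construct, but no label of a sample describes it. Each array carries its own replicate number within its group, and nothing states which mice bore which tumours. The tumours were treated as separate samples, so the p-values measure the spread between these tumours. If a mouse bore several of them, the p-values could be too small.

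Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.1. The deposited values are on a log2 scale, which was read from their range of about 3 to 14, and the background correction, normalization and summary method are not given in the sources used here. The table held 33297 rows for the 6 arrays without missing values. Gene names came from a table pairing the rows with the platform annotation. In it 19461 rows had 1 gene symbol, 1753 had several and 12083 were not listed, so that control rows could not be told from other unlisted rows. Of the rows with 1 symbol, 19429 matched a human RefSeq gene by gene ID, and no symbol needed updating. RefSeq names were used from the annotation of assembly GRCh38.p14 without its coordinates, because the deposited values name no genome build.

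Only rows with 1 symbol were tested, which gave 18418 genes. Of the 769 genes with more than 1 row, the row with the highest mean over the 6 arrays was used. Among called genes, 97 had several rows, and for 1 of them, ULK4, chosen for mention after its values were seen, rows passed the test in opposite directions. Dim genes were not filtered out. The deposited log2 values were compared between groups with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. YAP1 was also tested with an exact permutation test, for which 3 against 3 arrays allow no p under 0.1. Fold changes are given as Dox over No Dox on the log2 scale, with the standard error of the fit. The deposited table has no detection calls, so a level of 6.44, the 75th percentile of unlisted rows, was set after the values were seen as a guide to background. Of the 18418 genes tested, 7964 had both group means under this level. Unlisted rows may include control rows, so the level is a guide and not a limit of detection. A named gene with 1 group mean under it is given as at least the fold between the other group and that level, and one with both under it without a size, except in the lists of other cell types. Means of lists use the deposited values. The number of arrays limits the precision.

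Before the data were examined, 36 gene lists were fixed from textbook knowledge, with 3 of them as main lists: targets of YAP and TEAD, targets of Wnt and beta-catenin, and intestinal stem cell genes. Older symbols were matched through RefSeq, which gave CRIPTO for TDGF1 and MYL11 for MYLPF. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists tested. This test asks whether the genes of a list moved one way relative to all other genes. Beside it stand camera with a correlation estimated for each list, and fry, which asks whether the genes of a list moved, on balance, one way.

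The genes named were also set by rule before the data were examined. They are YAP1; the 12 largest rises and 12 largest falls among called genes whose 3 Dox values all lay on one side of the 3 No Dox values; the 4 members with the smallest unadjusted p of each called list and of the main lists; and CCN1, CCN2, ANKRD1, AMOTL2, AXIN2, LGR5, ASCL2, MYC, CCND1, MKI67 and WWTR1. Other list members named in the text were chosen after their values were seen.

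The procedure was tested on simulated data for the same 18418 genes, with the means and spreads of the 6 arrays and 50 genes changed at each of 4 fold sizes. The Dox against No Dox fit recovered 44% of genes changed 1.25-fold, 76% of those changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 3-fold, with 10 false calls among 166. In the list test, 10 of 10 simulated lists of 20 genes shifted by 0.3 were called, and 0 of 10 unshifted ones. The genes were simulated independently of each other. The simulation therefore does not show how the list test behaves where genes of a list are correlated. It also changed far fewer genes than the 2703 called in the real comparison. The unadjusted p needed for a call was therefore lower, so the recovered shares do not give the sensitivity of the real fit.

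The alternatives were quantile normalization, subtraction of array medians, cyclic loess, leaving out the dimmest 25% of genes, the mean of all rows of a gene, a mean-dependent or robust prior, array quality weights, a replicate block, and leaving out each array in turn. For the count of genes, all rows as separate features and a 1.5-fold minimum were tried as well, and for the lists camera on ranks. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Rows with several genes or none entered no comparison of named genes, and scanner files were not used here.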

Results

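Expression was compared between DLD1 xenograft tumours from mice given Dox for 21 days and tumours from mice given none. DLD1 is an established human colorectal adenocarcinoma line. The construct in the series title, YAP-S127D, denotes the transcriptional coactivator YAP with a serine replaced by aspartate. This serine is a site at which LATS kinases of the Hippo pathway phosphorylate YAP. Each group held 3 tumours with 1 array each. Array medians lay between 5.79 and 5.89 on the log2 scale. Over all rows, arrays of the same group correlated at a Pearson r of 0.996 to 0.998 and arrays of different groups at 0.994 to 0.996. These correlations are across rows, which are not independent replicates. The first principal component held 64.8% of the variance and separated the groups.

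YAP1, the gene of the construct, was measured first as a check of the labels. Its expression was 11.53 ± 0.03 (SD, n = 3) without Dox and 12.43 ± 0.05 (SD, n = 3) with Dox. This was a rise of 0.89 ± 0.05 (SE) on the log2 scale, or 1.86-fold, with a 95% confidence interval from 0.78 to 1.01 and a limma adjusted p of 4.06e-05. All 3 Dox tumours lay above all 3 No Dox tumours, and the exact permutation p was 0.1, the smallest that 3 against 3 can give. The array row does not tell the construct's transcript from that of the cells' own gene. All differences below are between tumours with Dox and a higher YAP1 level and tumours with neither. Effects of Dox itself and of YAP1 therefore cannot be told apart. WWTR1, which encodes the YAP paralog TAZ, differed by -0.23 ± 0.09 (SE; limma adjusted p = 0.149).

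With Dox, 1178 genes were higher and 1525 were lower among the 18418 tested, and 470 of these 2703 genes differed by at least 1.5-fold. The count fell to 1506 without Dox replicate 3 and to 1661 without No Dox replicate 1, and was 4269 with array quality weights. Of the 12 largest rises in the deposited values, 7 had a No Dox mean under 6.44, the 75th percentile of unlisted rows, and are given as at least the fold over that level, without an order. ANKRD1, a nuclear ankyrin repeat protein and widely used YAP target, rose at least 7.11-fold, and VGLL1, a cofactor of TEAD transcription factors, at least 4.74-fold. P3H2, a collagen prolyl hydroxylase, rose by 2.43 on the log2 scale, and the keratin gene KRT4 at least 3.68-fold. The matricellular genes CCN1 and CCN2 rose by 2.25 ± 0.26 (SE) and 1.83 ± 0.08 (SE). CCN1 varied more between tumours without Dox (SD 0.65) than with it (SD 0.07). HEG1 rose by 2.02 and the caveolar coat gene CAVIN1 by 1.90. The kinase gene RPS6KA6 rose at least 1.33-fold, the transcription factor gene ETS1 at least 1.99-fold, TMEM45A at least 2.72-fold and the carboxypeptidase gene CPA4 at least 1.39-fold. The adjusted p of these 12 genes lay between 3.68e-07 and 0.00104.

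CST1, a secreted cysteine protease inhibitor, fell from 10.72 ± 0.52 (SD, n = 3) to 7.41 ± 0.24 (SD, n = 3), or 9.90-fold lower with Dox. Log2 fold changes were -2.09 for the growth factor gene FGF20, -2.01 for KLHL4, -1.66 for LY6G6D, -1.60 for TMT1A and -1.44 for the mucin gene MUC13. The other 6 of the 12 largest falls had a Dox mean under 6.44. SLITRK6 was at least 4.60-fold lower, the cytosolic phospholipase gene PLA2G4A at least 3.84-fold, the urea transporter gene SLC14A1 at least 3.98-fold, the amino acid transporter gene SLC6A14 at least 3.58-fold and the fibrinogen gene FGA at least 1.06-fold. CRIPTO, which encodes a Nodal co-receptor, passed the test as lower but lay under that level in both groups, so no size is given. The adjusted p of the 12 genes lay between 1.01e-05 and 0.000395. Each of the 24 genes with the largest changes kept its direction and its call in every alternative.

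**Figure D1:**
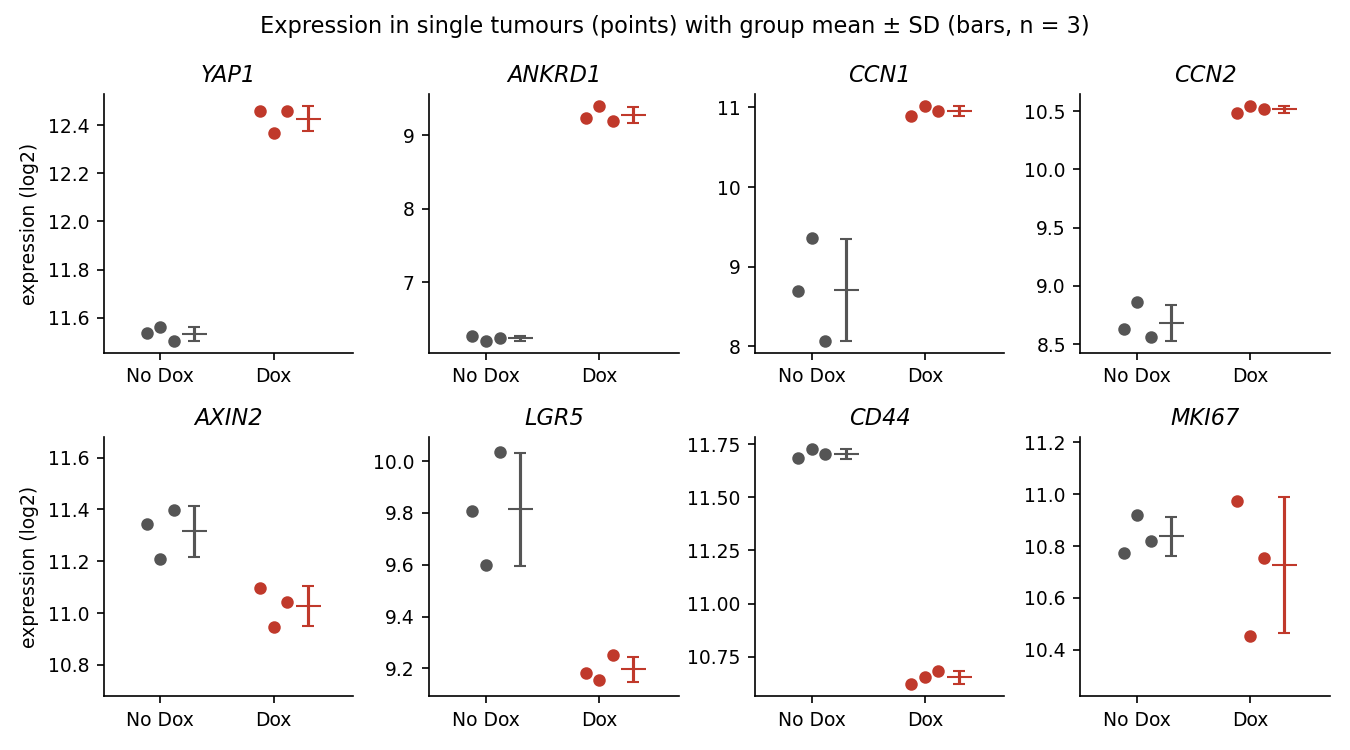
Expression on the log2 scale (vertical axes, each with its own range) of 8 genes in the 3 No Dox (grey) and 3 Dox (red) tumours, with points for single tumours and bars for the group mean ± SD. The groups lie apart for YAP1, ANKRD1, CCN1, CCN2, AXIN2, LGR5 and CD44, and overlap for MKI67.

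The targets of YAP and TEAD, the transcription factors through which YAP acts, moved up as a list. Of 22 measured members, 14 rose, 1 fell and 7 did not pass the test, and 17 passed when adjusted over the list alone. Besides ANKRD1, CCN1 and CCN2, F3, the gene of tissue factor, rose by 1.01 ± 0.06 (SE), GADD45B by 0.71 ± 0.07 (SE), and AMOTL2, which encodes an angiomotin that binds YAP, by 1.14 ± 0.14 (SE). RBMS3 rose at least 1.40-fold, and LATS2, an inhibitory kinase of YAP, by 0.62 on the log2 scale. NT5E was the member that fell (-0.27), and MYOF differed by 0.04 (adjusted p = 0.688). The mean shift was 0.72 ± 0.82 (SD over genes), with a camera adjusted p of 9.86e-11. The adjusted p was 0.163 with an estimated correlation.

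Targets of Wnt and beta-catenin moved down as a list, with 15 of 28 measured members lower, 1 higher and 12 not past the test. Adjusted over the list alone, 20 passed. CD44, an adhesion receptor, changed by -1.05 ± 0.05 (SE), TNFRSF19 by -1.09 ± 0.08 (SE), and SLC12A2, the sodium-potassium-chloride cotransporter gene, by -0.44 ± 0.06 (SE). CRIPTO was also lower. LGR5, the receptor that marks intestinal stem cells, fell by 0.62 ± 0.10 (SE), and the transcription factor gene ASCL2 fell by 0.56 ± 0.09 (SE). AXIN2, a feedback inhibitor of Wnt signalling, fell by 0.29 ± 0.07 (SE; limma adjusted p = 0.0240), and MYC fell by 0.27 ± 0.06 (SE; limma adjusted p = 0.0213). The call of AXIN2 was lost under cyclic loess and without No Dox replicate 1 or 3 or Dox replicate 2 or 3. That of MYC was lost with a replicate block and without No Dox replicate 1 or 2 or Dox replicate 1 or 3. The member that rose was PLAUR, by 0.32, while CCND1 differed by 0.19 ± 0.06 (SE; adjusted p = 0.0578) and passed after quantile normalization, after cyclic loess, with a mean-dependent prior and with array quality weights. The mean shift was -0.35 ± 0.47 (SD over genes), with a camera adjusted p of 2.74e-06, and the adjusted p was 0.250 with an estimated correlation.

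Intestinal stem cell genes were lower for 11 of 21 measured members, higher for 1 and not past the test for 9, and 14 passed when adjusted over the list alone. The list shares 11 measured genes with the Wnt targets, among them CD44, TNFRSF19, SLC12A2, LGR5 and ASCL2. PROM1 was the member that rose, by 0.80 ± 0.08 (SE). Camera gave an adjusted p of 0.000765, and the adjusted p was 0.320 with an estimated correlation.

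**Figure D2:**
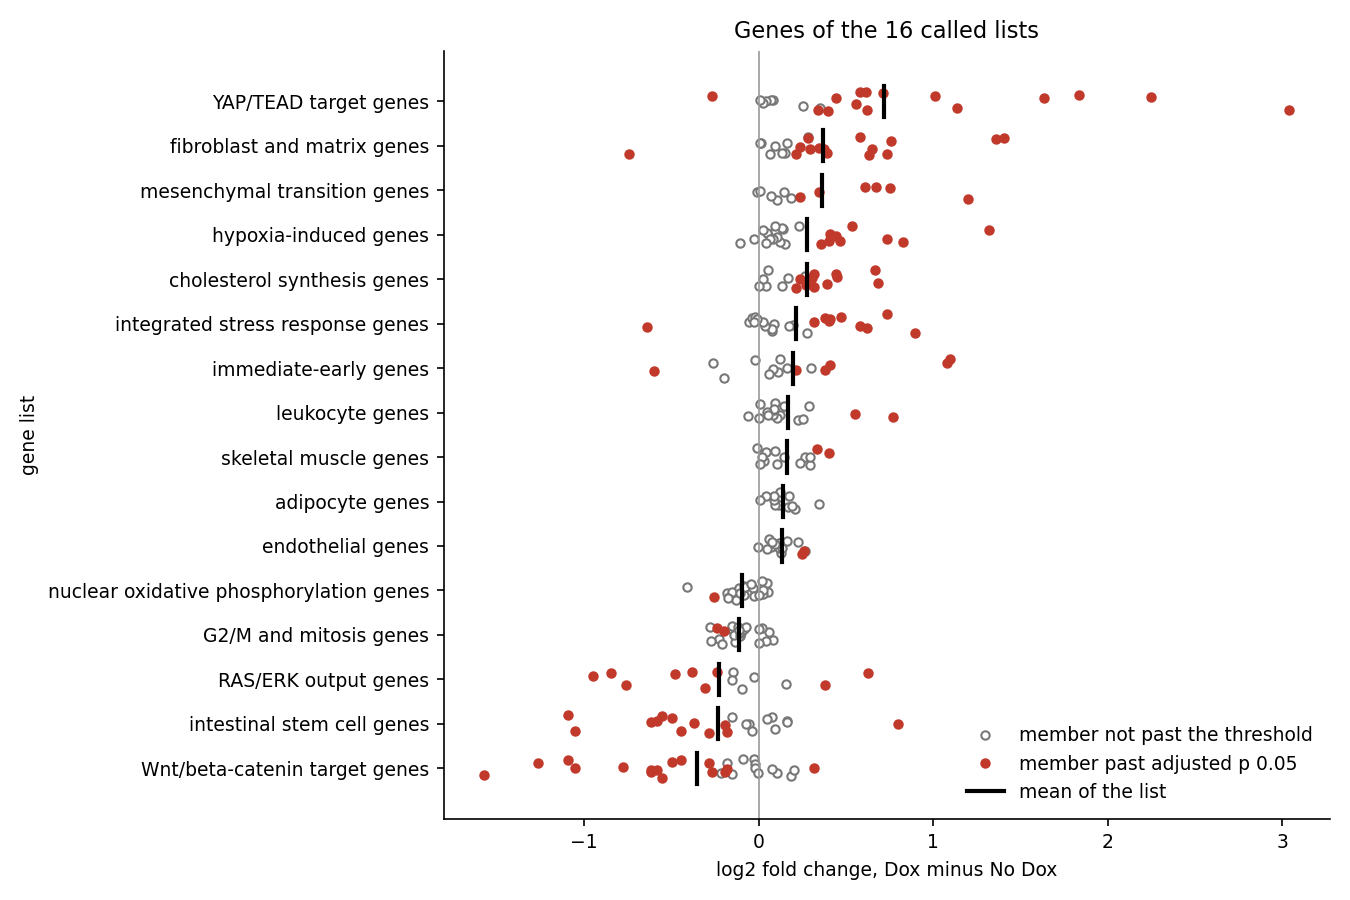
Log2 fold change (horizontal axis, Dox minus No Dox) of the measured members of the 16 called gene lists (vertical axis), with a point per gene, filled where it passed adjusted p 0.05, and a bar at the list mean. The mean is 0.72 for the YAP and TEAD targets and -0.35 for the Wnt targets, and each of these has a member past the test on the other side of 0.

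In all, 16 of the 35 tested lists were called, 11 upward and 5 downward. None was called with an estimated correlation, where the smallest adjusted p was 0.109 and 6 lists had an unadjusted p under 0.05, and fry called 15. No called list had a mean, median and test that differed in sign.

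Mesenchymal transition genes moved up, with 6 of 12 measured members higher, 0 lower and 6 not past the test, and 7 passing when adjusted over the list alone. The intermediate filament gene VIM rose by 0.67 ± 0.06 (SE) and TWIST1 by 0.35 ± 0.07 (SE). SNAI2 and ZEB2 passed the test as higher, and were among the 6 of 12 members with means under 6.44 in both groups. As a list, these genes had a camera adjusted p of 6.70e-05, and the adjusted p was 0.163 with an estimated correlation. In the same tumours the fibroblast and matrix list shifted by 0.37 ± 0.45 (SD over genes). Epithelial junction and keratin genes were not called (adjusted p = 0.683). In that list DSG2 fell by 0.39 and CDH17 fell by 0.55, 12 of 14 measured members did not pass the test, and 5 passed when adjusted over the list alone.

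Immediate-early genes moved up, with 5 of 15 measured members higher, 1 lower and 9 not past the test, and 9 passing when adjusted over the list alone. The phosphatase gene DUSP1 rose 2.14-fold. On the log2 scale, JUN rose by 1.08 ± 0.14 (SE) and KLF6 by 0.41 ± 0.08 (SE), while the nuclear receptor gene NR4A2 fell by 0.60 ± 0.08 (SE). For the list, camera's adjusted p was 0.0284, and the adjusted p was 0.484 with an estimated correlation. The call was lost without No Dox replicate 3 and with fry. Genes that report RAS and ERK output moved down, with 7 of 14 measured members lower, 2 higher and 5 not past the test, and 9 passing when adjusted over the list alone. The transcription factor genes ETV1 and ETV5 changed by -0.95 ± 0.08 (SE) and -0.85 ± 0.07 (SE), PHLDA1 by -0.48 ± 0.07 (SE) and the feedback inhibitor SPRY4 by -0.76 ± 0.11 (SE). DUSP5 rose by 0.62 and FOSL1 by 0.38. The camera adjusted p was 0.00302, and the adjusted p was 0.250 with an estimated correlation.

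Cholesterol synthesis genes moved up, with 11 of 18 measured members higher, 0 lower and 7 not past the test, and 13 passing when adjusted over the list alone. INSIG1, which retains the SREBP activation complex in the endoplasmic reticulum, rose by 0.68 ± 0.07 (SE). The enzyme genes MVD, DHCR7 and MSMO1 rose by 0.44 ± 0.05 (SE), 0.39 ± 0.06 (SE) and 0.32 ± 0.05 (SE). Camera gave an adjusted p of 5.93e-07, and the adjusted p was 0.250 with an estimated correlation.

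Hypoxia-induced genes moved up, with 9 of 24 measured members higher, 0 lower and 15 not past the test, and 9 passing when adjusted over the list alone. ANGPTL4, which encodes a lipase inhibitor, rose by 1.32 ± 0.14 (SE), the neuronal enolase gene ENO2 by 0.74 ± 0.10 (SE), the peptide hormone gene ADM by 0.83 ± 0.11 (SE) and the oxidase gene ERO1A by 0.35 ± 0.06 (SE). As a list, these genes had a camera adjusted p of 2.22e-05, and the adjusted p was 0.484 with an estimated correlation and 0.0795 with fry. Glycolytic enzymes were not called (adjusted p = 0.897), with 11 of 12 measured members not past the test and PFKM lower (-0.35 on the log2 scale). That gene was also the member that passed when adjusted over the list alone (1 gene).

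Integrated stress response genes, many of them induced by the transcription factor ATF4, moved up, with 9 of 23 measured members higher, 1 lower and 13 not past the test, and 11 passing when adjusted over the list alone. The stress transcription factor gene ATF3 rose at least 1.03-fold. On the log2 scale, the lipoprotein receptor gene VLDLR rose by 0.74 ± 0.11 (SE) and the asparagine synthetase gene ASNS by 0.62 ± 0.09 (SE), while CTH, an enzyme of cysteine synthesis, fell by 0.64 ± 0.08 (SE). For the list, camera's adjusted p was 0.000765, and the adjusted p was 0.320 with an estimated correlation. Endoplasmic reticulum chaperone genes were not called (adjusted p = 0.715), with 0 of 18 measured members past limma's test, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. Heat shock genes were not called either (adjusted p = 0.128), with 0 of 10 past limma's test, 0 when adjusted over the list alone and 2 at an unadjusted p under 0.05, although fry gave an adjusted p of 0.00998 and camera on ranks 0.0440.

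Shifts of proliferation and respiration genes were small. Of 24 measured G2/M and mitosis genes, 2 fell, 0 rose and 22 did not pass limma's test. When adjusted over the list alone 0 passed, against 7 at an unadjusted p under 0.05. The mitotic kinase genes BUB1 and TTK changed by -0.20 ± 0.05 (SE) and -0.24 ± 0.06 (SE), and CDK1 and ASPM differed by -0.23 ± 0.07 (SE; adjusted p = 0.0567) and -0.27 ± 0.08 (SE; adjusted p = 0.0580). MKI67 differed by -0.11 ± 0.12 (SE; adjusted p = 0.603). The mean shift of the list was -0.11 ± 0.10 (SD over genes), with a camera adjusted p of 0.00316 and an adjusted p of 0.295 with an estimated correlation. Of 23 measured nuclear oxidative phosphorylation genes, UQCRC2 fell by 0.26 ± 0.07 (SE) and 22 did not pass limma's test, with 0 passing when adjusted over the list alone and 6 at an unadjusted p under 0.05. NDUFV1 differed by -0.18 ± 0.06 (SE), NDUFS1 by -0.15 ± 0.05 (SE) and COX7B by -0.41 ± 0.14 (SE). The mean shift was -0.09 ± 0.11 (SD over genes), with a camera adjusted p of 0.0319 and an adjusted p of 0.726 with an estimated correlation. Both calls were lost under quantile normalization and cyclic loess, and the call of the respiration list also when the dimmest 25% of genes, No Dox replicate 2 or Dox replicate 1 was left out, and with fry. BUB1 lost its call under both normalizations, with a replicate block and without any array except No Dox replicate 2. TTK lost it under both, after subtraction of array medians and without any array except No Dox replicate 3 and Dox replicate 2. UQCRC2 lost it under cyclic loess, with a robust prior, with a replicate block and without any array except Dox replicate 2. G1/S and DNA replication genes (adjusted p = 0.983; POLA1 lower among 22) and ribosome biogenesis genes (adjusted p = 0.628; POLR1B and WDR12 lower among 19) were not called. Adjusted over the list alone, 0 and 2 of these genes passed limma's test, and 6 of each had an unadjusted p under 0.05. None of the 13 mitochondrially encoded genes had a row of its own, so that list was not tested.

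Genes of other cell types were measured because the tumours grew in mice and the array probes are human. Under 6.44 in both groups lay 15 of 23 fibroblast and matrix, 14 of 15 endothelial, 16 of 18 leukocyte, 9 of 14 skeletal muscle and 9 of 12 adipocyte genes, and the sizes of those genes are differences of deposited values near background. Genes under that level in 1 group only, among them COL1A2, COL3A1, EGFL7 and DES, have sizes that also depend on a value near background. COL1A1, CD68 and ACTA1 were among the genes above 6.44 in both groups. Fibroblast and matrix genes moved up, with 14 of 23 measured members higher, 1 lower and 8 not past the test, and 17 passing when adjusted over the list alone. The collagen genes COL1A2, COL1A1 and COL3A1 rose by 1.40 ± 0.09 (SE), 1.36 ± 0.13 (SE) and 0.63 ± 0.06 (SE), and MMP2 by 0.65 ± 0.05 (SE). The proteoglycan gene LUM fell by 0.74, and FN1 differed by 0.02. The camera adjusted p was 1.41e-09, and the adjusted p was 0.109 with an estimated correlation. The median level of this list was 5.48, against 4.64 for rows with no gene listed. Over all genes, the median log2 fold change was 0.06 in the fourth decile by expression level and -0.06 in the seventh.

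Endothelial genes shifted by 0.13 ± 0.08 (SD over genes), with 2 of 15 measured members higher, TIE1 by 0.26 ± 0.06 (SE) and ENG by 0.25 ± 0.06 (SE), 0 lower and 5 passing when adjusted over the list alone. Both calls were lost after quantile normalization, with a replicate block and without No Dox replicate 1 or 2 or Dox replicate 3. That of TIE1 was also lost under cyclic loess and without No Dox replicate 3 or Dox replicate 1, and that of ENG without Dox replicate 2. EGFL7 differed by 0.27 ± 0.08 (SE) and KDR by 0.16 ± 0.05 (SE). Camera gave an adjusted p of 0.00314, and the adjusted p was 0.240 with an estimated correlation. Leukocyte genes shifted by 0.17 ± 0.20 (SD over genes), with 2 of 18 higher and 0 lower, and the same number passing when adjusted over the list alone (2 genes). The macrophage receptor gene CSF1R rose by 0.55 ± 0.06 (SE) and the lysosomal gene CD68 by 0.77 ± 0.13 (SE), and CD14 differed by 0.29 ± 0.09 (SE) and CYBB by 0.22 ± 0.08 (SE). As a list, these genes had a camera adjusted p of 0.00323, and the adjusted p was 0.320 with an estimated correlation. Skeletal muscle genes shifted by 0.16 ± 0.14 (SD over genes), with MYL11 and ACTA1 higher by 0.33 ± 0.06 (SE) and 0.40 ± 0.07 (SE) and 12 of 14 not past the test. DES differed by 0.26 and NEB by 0.29, and 2 members passed when adjusted over the list alone. For the list, camera's adjusted p was 0.00595, and the adjusted p was 0.295 with an estimated correlation. Adipocyte genes shifted by 0.14 ± 0.09 (SD over genes) with 0 of 12 past limma's test, also when adjusted over the list alone, and 5 at an unadjusted p under 0.05. PLIN1, LPL, LIPE and RETN differed by 0.34, 0.21, 0.17 and 0.19. The camera adjusted p was 0.0137, the adjusted p was 0.295 with an estimated correlation, and the call was lost without Dox replicate 1. Keratinocyte genes (adjusted p = 0.195; 0 of 11 past the test) and erythroid genes (adjusted p = 0.761; 0 of 6) were not called. In limma's fit 0 of both passed when adjusted over the list alone, and 2 and 1 had an unadjusted p under 0.05. Of these genes, 10 of 11 and 6 of 6 lay under 6.44 in both groups.

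Intestinal differentiation lists were not called, and most of their members had little signal, with 19 of 24 enterocyte and colonocyte, 10 of 16 goblet cell, 12 of 14 enteroendocrine and 7 of 8 Paneth cell genes under 6.44 in both groups. In the enterocyte and colonocyte list (adjusted p = 0.741), 3 of 24 measured members rose, 3 fell and 18 did not pass the test, and 6 passed when adjusted over the list alone. CA2, a carbonic anhydrase gene, rose by 0.76 ± 0.07 (SE) and the peptidase gene DPP4 by 1.06 ± 0.14 (SE), while the microvillus gene VIL1 changed by -1.05 ± 0.16 (SE), CEACAM1 was at least 1.80-fold lower and the glucose transporter gene SLC5A1 was lower with means under 6.44 in both groups. Among 16 goblet cell genes (adjusted p = 0.983), the transcription factor gene SPDEF fell by 0.71 ± 0.12 (SE), GFI1 and CREB3L1 passed as higher with means under 6.44 in both groups, and the count adjusted over the list alone was also 3. Of 14 enteroendocrine genes (adjusted p = 0.454), SCG5 fell by 0.87 ± 0.15 (SE), and of 8 Paneth cell genes (adjusted p = 0.676), 0 passed limma's test. Adjusted over the list alone, 1 and 0 passed, against 2 and 1 at an unadjusted p under 0.05. Of the 19 lists tested and not called, 7 had a mean, a median and a test that differed in sign. Among them were the enterocyte, goblet cell, G1/S, glycolytic and epithelial junction lists.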

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

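YAP1 kept its rise and its call under every alternative, between 0.88 and 0.92 on the log2 scale. The count of 2703 called genes moved to 4269 with array quality weights (1913 higher, 2356 lower). The weights were 2.80 for Dox replicate 3 and 1.76 for No Dox replicate 1, against 0.63 to 0.70 for the other arrays. That fit thus leans on these arrays, though the cause of the higher count was not tested. With a 1.5-fold minimum, a stricter threshold by construction, the count was 470 (247 higher, 223 lower). Leaving out 1 array gave 1506 to 2301 genes, of which 667 to 1024 were higher and 839 to 1387 lower, with fewer samples in the fit. The lowest counts came without Dox replicate 3 and, at 1661, without No Dox replicate 1. Quantile normalization gave 2426 genes and cyclic loess 2445, with 2168 and 2194 of the 2703 called again, and 49.2% and 49.4% of calls higher, against 43.6% as deposited.

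The shifts of the 3 main lists kept their direction and call except with an estimated correlation, where the adjusted p was 0.163 for YAP and TEAD targets, 0.250 for Wnt targets and 0.320 for stem cell genes, and 0 of the 16 lists remained called. That setting rests on the few residual degrees of freedom of 6 arrays, which widens the test by construction. This held also for the fibroblast list, whose estimated correlation of 0.0124 was close to the preset. For the 3 main lists the estimated correlations were 0.114, 0.123 and 0.158, above the preset of 0.01. Their weaker results thus also reflect correlation between genes that the preset leaves out. The same holds for the hypoxia and respiration lists, whose estimated correlations were 0.511 and 0.442. Apart from the setting with an estimated correlation, the highest adjusted p were 0.00103, 0.00651 and 0.0114. Leaving out 1 array gave 15 to 17 called lists and adjusted p of 1.32e-12 to 3.39e-09, 4.49e-07 to 1.72e-05, and 0.000259 to 0.00180 for the 3 main lists. Camera takes no robust prior, so that alternative was not run for lists.

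Of 72 other named genes past the threshold, 65 kept direction and call in every alternative that tested them; BUB1, TTK, UQCRC2, TIE1, ENG, AXIN2 and MYC each lost the call in some. Of those not past it, 11 passed in some alternative, and MKI67 ranged from -0.23 to 0.027 when 1 array was left out, reversing without Dox replicate 2; the cause was not tested. With a replicate block 1846 genes and 16 lists were called. No label says that the numbers pair the tumours. Deviations of same-numbered arrays correlated at -0.24, -0.03 and 0.00, and 0 of 3 No Dox arrays correlated best with its own number. These values show no sign of a pairing, but 3 arrays per group are too few to exclude one. Genes near the level of unlisted rows have little signal over background. Of the 2703 called genes, 192 had 1 group mean under 6.44 and 519 had both. This limits the sizes of many large changes, among them those of VGLL1, RPS6KA6, CPA4, FGA and CRIPTO. It also limits the mesenchymal transition list and the lists of other cell types.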

Other observations

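The tests of the actin and fatty acid lists and of other splits of the arrays were set before their results were seen, and those of the fibroblast, other cell type, proliferation, respiration and stem cell lists only after. Hippo pathway components were not called as a list (camera adjusted p = 0.233), but 5 of 20 measured members rose and 1 fell, with 7 past the test when adjusted over the list alone. AMOTL2 and LATS2, which are also YAP targets, rose by 1.14 and 0.62, AMOT by 0.63, the transcription factor gene TEAD4 by 0.51 and the scaffold gene SAV1 by 0.39, while TEAD2 fell by 0.59. The list was called after quantile normalization, after cyclic loess and without Dox replicate 2. Genes of TGF-beta and BMP response went both ways (adjusted p = 0.333; fry 0.0343). The pseudoreceptor gene BAMBI and the BMP targets ID1 and ID3 fell, with log2 fold changes of -0.71, -0.52 and -0.58, while PMEPA1 rose by 0.66, and 5 of 9 did not pass the test, while 5 passed when adjusted over the list alone. Among 13 Notch pathway genes (adjusted p = 0.336), NOTCH1 and its ligand gene DLL4 fell (-0.50 and -0.32), and HES4 rose by 0.39 and HEYL, near background, passed as higher, with 8 past the test when adjusted over the list alone.

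Of 27 interferon-stimulated genes (adjusted p = 0.148), OAS1, IFI27 and IFIH1 fell, at -1.08, -0.92 and -0.35, and IRF7 rose by 0.35, with 5 past the test when adjusted over the list alone. The list was called lower with array quality weights (adjusted p = 0.00947) and without No Dox replicate 2 (0.0203) or Dox replicate 1 (0.00286). In the NF-kB and cytokine list (adjusted p = 0.761), the cytokine gene LIF rose by 0.93, RELB by 0.24 and NFKB2 by 0.37, and the chemokine gene CXCL5 fell (-0.63), as did CXCL2, near background; adjusted over the list alone, 6 of 20 passed. NRF2 targets (adjusted p = 0.983) split into AKR1C3, GCLC and NQO1, which fell (-1.06, -0.44 and -0.40), and ME1, HMOX1 and SRXN1, which rose by 0.33, 0.32 and 0.23; adjusted over the list alone, 7 of 15 passed. Among 18 p53 targets (adjusted p = 0.996), 3 rose, with GADD45A at 0.48, and 4 fell, among them TP53INP1, and 11 passed when adjusted over the list alone. Rows that name several genes or none entered no comparison above. With all 33297 rows in one limma fit, 5.65% of rows with several genes and 1.62% of unlisted rows were called, against 8.79% of rows with 1 gene.

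CAVIN1 and ACTA2 rose by 1.90 and 0.76 and TAGLN at least 1.58-fold, which gave the hypothesis that genes of the actin cytoskeleton, many of them targets of serum response factor, rose as a group. A list of 26 such genes, without those already seen, had 22 measured members, of which 12 rose and 0 fell. The mean shift was 0.28 ± 0.22 (SD over genes), with TPM1 at 0.82, MYL9 at 0.70, CNN3 at 0.57 and FHL2 at 0.44. The unadjusted camera p was 3.42e-10, and with an estimated correlation the unadjusted p was 0.00305. These values are consistent with the hypothesis, while SRF itself differed by 0.20 (adjusted p = 0.0679) and ACTB by 0.08. Among the 12 genes that rose, FERMT2, CNN1 and TPM2 had mean levels over all arrays of 4.50, 5.78 and 6.37, under 6.44. The hypothesis came from the same arrays, so the test is not an independent check of it. Whether the tumour cells or host cells carried the rise was not tested.

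A second hypothesis was that fatty acid synthesis genes, which SREBP factors also induce, rose with the cholesterol synthesis genes. Of 15 measured genes 4 rose, PNPLA3, SCD, FADS1 and ACSS2, and GPAM fell by 0.20, while FASN differed by 0.09 and ACLY by 0.00. The mean shift was 0.13 ± 0.26 (SD over genes), and the unadjusted camera p of 0.0525 leaves the question open. That p was 0.00639 after cyclic loess, 0.00643 after quantile normalization and 0.107 with an estimated correlation. The unadjusted p of fry was 0.00609.

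The rise of fibroblast and matrix genes may come from the tumour cells, from mouse stroma read by human probes, or from processing. Dim genes were slightly higher and bright genes slightly lower with Dox, with a median shift of 0.06 in the fourth decile of genes by level and -0.06 in the seventh. Quantile normalization brought these medians to 0.003 and -0.009, and cyclic loess reduced them to 0.020 and -0.019. After these corrections the list kept 92.9% and 93.2% of its mean shift, with a camera adjusted p of at most 7.52e-09. This argues against the trend as the whole cause. A larger share of all host cells could not be told apart from a change in fibroblasts or tumour cells: only 4 fibroblast and matrix genes and 2 endothelial or leukocyte genes had means above the 75th percentile of unlisted rows (6.44) in both groups, too few to compare (permutation p = 0.802). COL1A1, at 9.42 ± 0.10 (SD, n = 3) with Dox, was the brightest of them, and ACTA2 and TAGLN are also smooth muscle genes.

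The same trend was tested on the small shifts of other lists. After the corrections the mean shift of G2/M genes shrank from -0.11 ± 0.10 (SD over genes) to -0.07 ± 0.10 under both, and that of respiration genes from -0.09 ± 0.11 to -0.06 ± 0.11 and -0.05 ± 0.11, and both calls ended because the shifts shrank (lowest adjusted p 0.0672). An intensity-dependent difference between the arrays is thus a candidate explanation for part of these falls. The skeletal muscle list kept 87.2% and 85.5% of its shift with an adjusted p of at most 0.0314, which argues against the trend as its whole cause. The endothelial, leukocyte and adipocyte lists stayed called, with an adjusted p of at most 0.0397, but the endothelial shift fell to 67.9% of its size after quantile normalization, so the part played by the trend stays open. Effects of doxycycline itself and of the higher YAP1 level stay open for these lists, as for every gene and list here. They were not tested apart, since no tumour had one without the other.

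The fall of the intestinal stem cell list may rest on the genes it shares with the Wnt targets. The 11 shared genes shifted by -0.51 ± 0.32 (SD over genes), with 10 lower, and the 10 others by 0.08 ± 0.30, with PROM1 higher and CDCA7 lower (camera p of the others 0.253). The parts differ in level, however. All 11 shared genes had means above 6.44 in both groups, but only 3 of the others did, and the remaining 7 had little signal over background that a fall would show in. As measured, the fall of the list thus lay in the shared genes. Whether the 7 genes with little signal also fell stays open.

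Of the 10 ways to split the 6 arrays into groups of 3, only the real one (1 split) gave 2703 called genes, and the highest other limma count was 0, with up to 837 genes at an unadjusted p under 0.05 against 5290. For gene lists the real split called 16 and the highest other split 10, and 1 split reached the real count. Every other split had tumours of both groups on each side, so the difference between the groups widened the spread within each side. Low gene counts in those splits are therefore partly built in. A total of 10 splits is also too few for a share under 0.05.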
